A study of Rattus norvegicus with 6 samples.

How the data were processed

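Total RNA of the renal cortex of 6 male Sprague-Dawley rats, 3 given corn oil and 3 given 1,2-dibromoethane, was labelled with Cy3 and hybridised to single-colour Agilent arrays, per the labels' protocols. The labels describe 3 animals per group, so that each array is a separate animal. The deposited scanner tables hold intensity values per spot; per the file headers they were made with Agilent Feature Extraction 10.7.1.1 on array design 045522, whose grid names genome build rn4. The processed signal in them is background-subtracted by that program, per the file headers. The deposited series table holds intensity values too; set against the scanner values it equals each array's processed signal divided by that array's 75th percentile (r = 1.000 on the log2 scale for all 6 arrays), on a linear scale with no centring of genes. Its column medians were 0.102, 0.103, 0.112, 0.110, 0.106 and 0.107 for control replicates 1 to 3 and dibromoethane replicates 1 to 3. The submitters' processing notes name Feature Extraction 10.7.

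Of 62976 spots per array, 1439 control spots were left out of all tests, as were 84 ERCC spike-in probes, of which 3 to 10 per array were well above background. The other 61453 probes were analysed. The scanner tables used here pair probes with accessions and not with gene names; accessions without versions were matched to a RefSeq gene table of the assembly GRCr8, which differs from rn4 and served only for names and for which genes neighbour each other. In this way 28206 probes (45.9%) received 1 of 15645 gene symbols, and 33247 probes are unnamed here. The main values were log2 of the processed signal minus the array's 75th percentile over probes that are not controls. Spots flagged as outliers, 1 to 11 per array, were set to missing, and saturated spots were kept (there were 0). A gene with several probes was represented by the probe with the highest mean signal, and an unmatched probe stood for itself. A feature was tested if it was well above background on all arrays of at least 1 group, which left 28961 features, 11427 with a symbol and 17534 without. Where a probe was not well above background on any array of a group, the fold is a lower bound: the mean of the bright group against the mean, per array of the dim group, of the higher of the probe's own value and the lowest signal among probes well above background.

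Treated and control arrays were compared with lmFit and eBayes in limma 3.58.1 (R 4.3.3; 4 residual and 2.05 prior degrees of freedom), without covariates, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Gene lists, 26 in number with 538 entries, were fixed before the data were examined; 1 entry matched no gene of the table. The 25 lists with at least 5 measured members were tested with camera at a preset correlation of 0.01, and beside it with an estimated correlation and with fry; Benjamini-Hochberg adjustment ran over the lists. With an estimated correlation 0 lists passed, as with the directional test of fry, while the test of fry for change in either direction passed 12. Members adjusted over a list alone were adjusted within that list, with no correction across lists. No list member passed over all features. List names stand for the members chosen, and a list's median, mean and camera direction differed in sign for NRF2 targets, cytochrome P450, cell cycle, DNA repair, endothelial and heat shock lists, none of which passed. The lists for other cell types were thick ascending limb, distal tubule and collecting duct, podocyte, endothelial, macrophage, lymphocyte, blood cell, perirenal fat, adrenal and inner medulla markers.

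The genes named in the text followed a rule fixed before the data were examined. It took called genes with a symbol that do not overlap between the groups, up to 12 per direction by size, with up to 4 more where 1 group was not well above background; where under 5 passed in a direction, the 5 with the smallest p as values; up to 4 called members per list, or else the 2 with the smallest p; and 15 markers of kidney injury, DNA damage response and metabolism of the compound. Acot2, Angptl4, Pdk4, Fabp1, the unnamed probes and all genes named only in the closing section were chosen after their values were seen.

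The arrays lay on 3 slides: slide 1 held control replicates 1 and 2 and dibromoethane replicate 2, slide 2 control replicate 3 and dibromoethane replicate 1, and slide 3 dibromoethane replicate 3. Slides 1 and 3 were scanned on one day and slide 2 on another. Alternatives fixed before the data were examined were quantile normalization, median centring, normexp background correction with an offset of 50, no filter on dim probes, a filter on all 6 arrays, the mean of a gene's probes, each probe by itself, slide as a fixed or random block, only slides with both groups, the replicate number as a block, eBayes with trend and robust, array weights, the deposited series table and leaving out each array. The median signal of a spot took the place of its mean signal in normexp, since the mean signal was not used here. The fit and the list test were tested on simulated data with the real means and spreads of 28950 features. Each feature was drawn independently, so that the simulation cannot show how the list test behaves where members are correlated. In the real data the estimated correlation of the fatty acid oxidation list was 0.270. Of 50 features each changed by 0.5, 1, 2 and 3 on the log2 scale, 12.0%, 60.0%, 80.0% and 100.0% were recovered, with 5 false calls. These shares depend on how many features were changed, since the adjustment is milder where more features pass. They are therefore not the power of the real comparison. There 361 features differed at least 2-fold, of which 7 passed. A simulated list shifted by -0.3 was found (camera adjusted p = 3.74e-16) with 0 other lists. No pair of arrays held the same values. Figures were drawn with matplotlib 3.10.9.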

Results

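Gene expression was measured in the renal cortex of 6 male Sprague-Dawley rats, an outbred strain bought at 5 weeks of age. For 4 weeks, 3 rats received corn oil (the control group) and 3 received 75 mg/kg/day of 1,2-dibromoethane, a halogenated solvent and former soil fumigant that is metabolised by cytochrome P450 and by glutathione conjugation. Each animal gave 1 single-colour array of 62976 spots, of which 61453 probes were analysed. Between 59.2% (dibromoethane replicate 2) and 67.7% (dibromoethane replicate 1) of the probes that were not controls were well above background, and none was saturated. The number of arrays, 3 per group, limits the precision of each difference. Pairs of arrays of 1 group correlated at r = 0.989 to 0.993 over the tested features, and pairs of different groups at r = 0.988 to 0.992, both across genes, which are not independent replicates.

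The comparison asks which transcripts of the renal cortex differed between dibromoethane-treated and corn oil rats. Among features with a gene symbol, those that passed the test were class I genes of the RT1 complex, the major histocompatibility complex of the rat, and a neighbour of it. RT1-CE15 rose 7.15-fold, from a log2 level of -3.52 ± 0.09 (SD, n = 3) relative to the array's 75th percentile in controls to -0.68 ± 0.05 (SD, n = 3) in treated rats (log2 fold change 2.84, SE 0.08, limma adjusted p = 0.000701; log2 fold change 2.08 with normexp background correction). RT1-A3 was not well above background on any control array and was well above it on all 3 treated arrays, at least 2.2-fold higher (limma adjusted p = 0.0193). Vps52, a subunit of a complex that tethers vesicles to the Golgi, rose 1.89-fold (log2 fold change 0.92, SE 0.07, limma adjusted p = 0.0403), and its other probe above background on all arrays gave 0.75. By gene order in the GRCr8 assembly these 3 genes all lie in or beside the RT1 region. RT1 class I genes resemble each other in sequence, and binding of a probe to transcripts of a related gene was not tested.

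**Figure D1:**
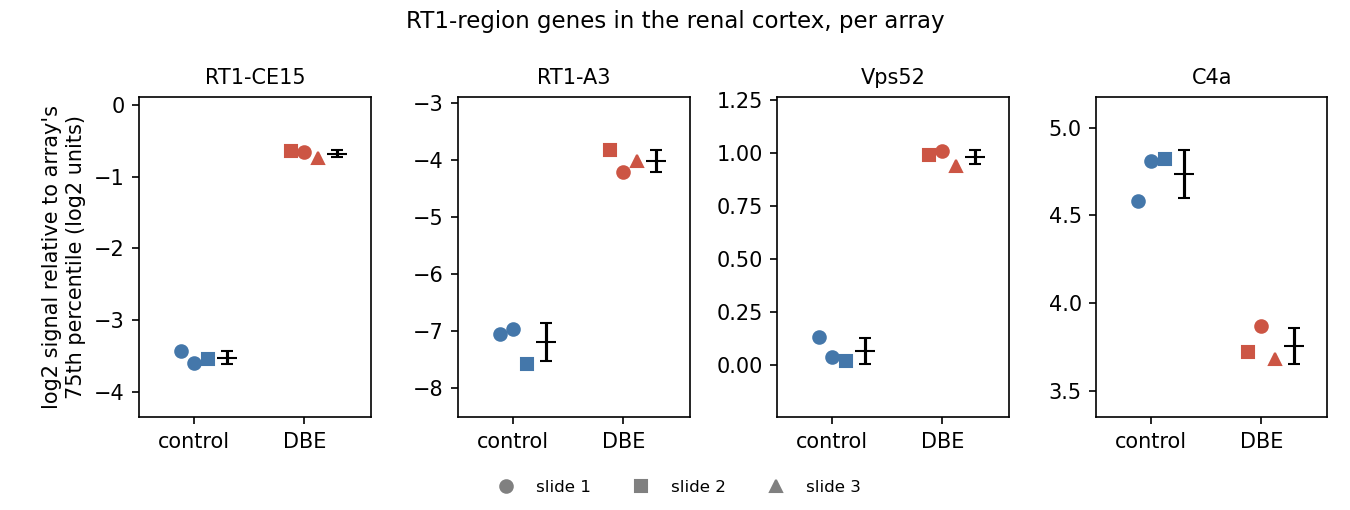
Log2 signal relative to each array's 75th percentile (y axis) for 4 genes of the RT1 region in control and dibromoethane (DBE) rats (x axis); each symbol is 1 array, its shape gives the slide, and the bar is the mean with 1 SD (n = 3). Treated arrays lie between -0.74 and -0.64 for RT1-CE15, above the control arrays at -3.59 to -3.42; for RT1-A3 the control arrays are not well above background, and C4a did not pass the test (limma adjusted p = 0.11).

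In all, 9 of 28961 features passed an adjusted p of 0.05 in limma, 7 raised and 2 lowered, and 7 of the 9 differed at least 2-fold. Of the 9, 3 have a gene symbol here. Among the others, the probe A_44_P118475 was at least 8.7-fold higher in treated rats (limma adjusted p = 0.0065). A_42_P453976 was 3.27-fold higher (limma adjusted p = 0.0135), and C_CA_B0056 and A_44_P1020311 were lowered (log2 fold change -1.28 and -0.85). Of all features, the 9 included, 3237 (11.2%) had an unadjusted p under 0.05, 1313 higher and 1924 lower, where chance gives 1448. In 19.5% of features the groups did not overlap, where chance gives 10%. Neither chance value takes account of the slides. Splitting the arrays as slide 1 against slides 2 and 3 gave 4953 features at an unadjusted p under 0.05 in limma. The other splits into 3 and 3 that mix the groups gave 621 to 1198. The count of 9 was 4 without control replicate 1, 1 without control replicate 2, 8 without control replicate 3, 1 without dibromoethane replicate 1, 1 without dibromoethane replicate 2 and 7 without dibromoethane replicate 3. Of these, 3, 1, 4, 1, 1 and 2 were among the 9. RT1-CE15 passed in each of these 6 fits, RT1-A3 only without control replicate 3 and Vps52 in none. With normexp background correction, whose offset of 50 shrinks differences of dim probes, the log2 fold change was 1.80 for A_44_P118475, 1.13 for A_42_P453976 and 0.78 for RT1-A3, which then did not pass. Vps52 (0.82) did not pass with normexp either (limma adjusted p = 0.063), nor with the mean of its probes (limma adjusted p = 0.0883). With normexp, 4 of the 9 passed. With slide as a fixed block, which leaves 2 residual degrees of freedom, 0 features passed in limma (3511 at an unadjusted p under 0.05), and with slide as a random block 11 passed. The difference of RT1-CE15 was 2.87 with the fixed block, 2.84 within slide 1 and 2.90 within slide 2, and that of Vps52 was 0.94, 0.93 and 0.96. RT1-A3 was at least 1.8-fold higher within slide 1 and at least 3.1-fold within slide 2.

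The genes with the 5 smallest p in each direction include some that did not pass the adjusted threshold. On the higher side, after the 3 genes above, these were Tph1, the peripheral tryptophan hydroxylase (log2 fold change 1.06, SE 0.11), and Itpka, an inositol trisphosphate kinase (0.80, SE 0.08), both at an adjusted p of 0.11. On the lower side stood the complement gene C4a, also of the RT1 region (-0.98, SE 0.10, adjusted p = 0.11), the cell cycle regulator Rgcc (-1.05, SE 0.11, adjusted p = 0.11), the natural killer cell receptor genes Klrc3 (-1.46, SE 0.16) and Klre1 (-1.45, SE 0.17), and Zfp763 (-0.71, SE 0.08).

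Genes of fatty acid oxidation and targets of PPAR-alpha, the nuclear receptor that drives lipid catabolism, were lower as a group. Of 24 measured members 23 had a negative log2 fold change, with a median of -0.33 (camera adjusted p = 2.81e-07 over 25 lists; adjusted p = 0.443 with an estimated correlation). Over all genes 0 members passed, and 4 were lowered when adjusted over the list alone. Those 4 were Eci1, an isomerase of unsaturated fatty acid oxidation (log2 fold change -0.65, SE 0.11), the long-chain dehydrogenase Acadl (-0.34, SE 0.07), the thioesterase Acot2 (-0.45, SE 0.10) and Angptl4, an inhibitor of lipoprotein lipase (-1.02, SE 0.25). The value of Pdk4, a kinase that restrains glucose oxidation, was -1.54 (SE 0.49). Fabp1, the liver fatty acid binding protein, was the 1 member with a positive value (1.83, SE 0.99). Transcripts abundant in liver, a list written after these results were seen, were higher in treated arrays for 22 of 23 members, with a median log2 fold change of 0.63. The median of the fatty acid oxidation list was -0.40 within slide 1, -0.17 within slide 2, -0.29 with slide as a fixed block and -0.21 without control replicate 2.

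Blood cell markers were lower too, with 6 of 7 measured members negative, a median of -0.43 (camera adjusted p = 0.00317; adjusted p = 0.443 with an estimated correlation) and 4 lowered when adjusted over the list alone. The beta-globin gene Hbb had a log2 fold change of -0.43 (SE 0.10) and Alas2, the erythroid enzyme of haem synthesis, one of -0.52 (SE 0.14). The median was -0.18 within slide 1, -0.71 within slide 2 and -0.40 with slide as a fixed block.

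**Figure D2:**
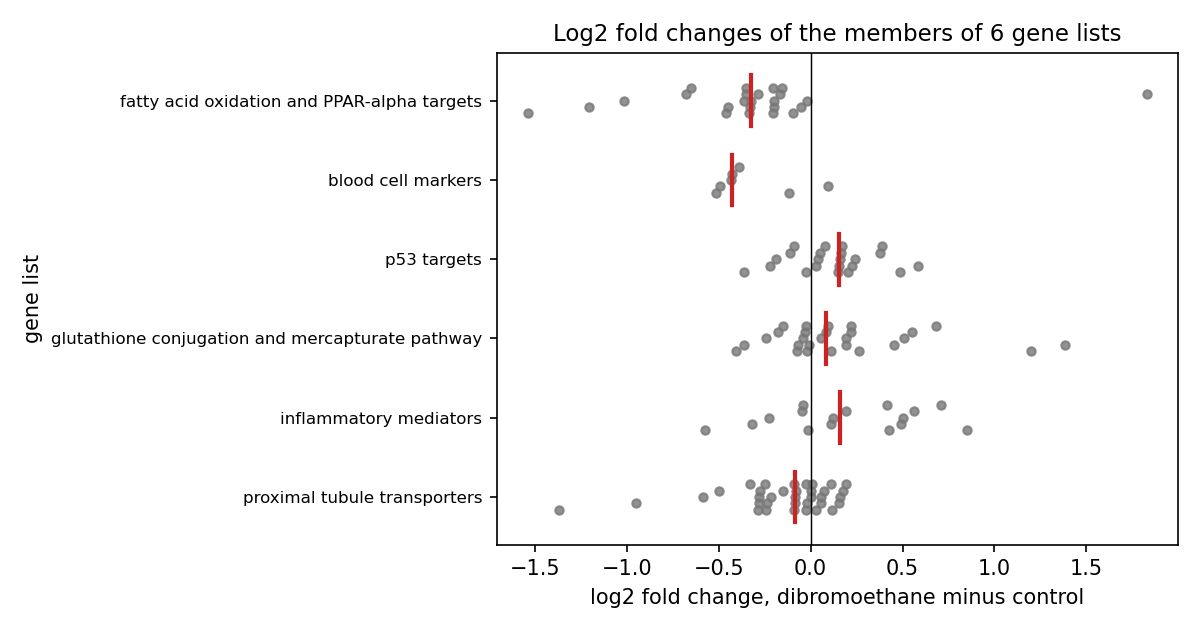
Log2 fold change, dibromoethane minus control (x axis), of each measured member (grey points) of the 5 lists that passed camera and of the proximal tubule transporters (y axis, points spread vertically for legibility), with the list's median as a red line. Of the fatty acid oxidation members, 23 of 24 lie below 0; the proximal tubule transporters have a median of -0.09, which is 0.01 under quantile normalization.

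Targets of p53, the transcription factor activated by DNA damage, were raised as a list: 16 of 22 members were positive, with a median of 0.15 (camera adjusted p = 0.0276; adjusted p = 0.443 with an estimated correlation). Ephx1, microsomal epoxide hydrolase, rose when adjusted over the list alone (log2 fold change 0.59, SE 0.09), but did not pass over all features (limma adjusted p = 0.222). Gadd45a had a value of -0.36 (SE 0.10). The classical targets gave 0.21 (SE 0.09) for Mdm2, with -0.02 from its other probe, 0.23 (SE 0.12) for Ccng1, with 1.07 from its other probe, and -0.11 (SE 0.15) for Cdkn1a, with 0.08 from its other probe. The median of the list was 0.19 within slide 1, 0.05 within slide 2 and 0.16 with slide as a fixed block. The call was lost without control replicate 1 (median 0.07), without dibromoethane replicate 2 (median 0.07), with array weights (median 0.12) and on only the slides with both groups (median 0.16). With each probe by itself the median was 0.08, and with the mean of a gene's probes 0.09.

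Glutathione conjugation and mercapturate pathway genes were also raised as a list, with 15 of 27 members positive and a median of 0.08 (camera adjusted p = 0.0435; adjusted p = 0.443 with an estimated correlation). None of its members passed when adjusted over the list alone. Gstm3 was not well above background on any control array and was on all 3 treated arrays, at least 2.0-fold higher (limma adjusted p = 0.251), and Gstt1, a theta class transferase, had a value of 0.55 (SE 0.16), with 0.22 (SE 0.09) for Gsta1. The list's median was 0.20 within slide 1, 0.10 within slide 2 and 0.13 with slide as a fixed block. The call was lost without control replicate 1 (median 0.10), without control replicate 3 (0.02), without dibromoethane replicate 2 (0.05), with array weights (0.03), with the filter on all 6 arrays (0.07) and with scan day as a fixed block (0.08). The median was 0.15 without dibromoethane replicate 1, 0.03 with each probe by itself and 0.02 on scan day 1 alone.

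Inflammatory mediators were the third raised list, with 10 of 16 members positive and a median of 0.16 (camera adjusted p = 0.0276; adjusted p = 0.443 with an estimated correlation). Ccl2, a monocyte chemoattractant, rose 1.80-fold (log2 fold change 0.85, SE 0.11) and Csf1, the macrophage growth factor, 1.42-fold (0.50, SE 0.07) when adjusted over the list alone. Over all features neither passed (limma adjusted p = 0.190 and 0.196). The median was 0.26 within slide 1, 0.02 within slide 2 and 0.15 with slide as a fixed block. The call was lost without control replicate 1 (median 0.21), and the median was 0.24 without control replicate 3. Macrophage and myeloid markers did not pass (median -0.11, camera adjusted p = 0.131). Among them C1qb fell by 0.48 on the log2 scale (SE 0.09) when adjusted over the list alone, but did not pass over all features (limma adjusted p = 0.248). C1qa stood at -0.54 (SE 0.13).

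Of the lists on the response to toxicants, tubular injury and repair did not pass (13 of 21 positive, camera adjusted p = 0.158). Values in it were 0.45 (SE 0.12) for Hbegf, 0.63 (SE 0.37) for Clu, 0.48 (SE 0.25) for Spp1 and 0.17 (SE 0.34) for Lcn2. The fibrinogen gene Fgg, which is made in liver as well, had a value of 2.52 (SE 0.90), beside the liver transcripts' median of 0.63. Havcr1, which encodes kidney injury molecule 1, was well above background on 4 of the 6 arrays and was not tested; dibromoethane replicate 2 had the highest log2 level, -2.68, and the other 5 arrays lay between -5.58 and -4.62. NRF2 targets, genes of the antioxidant response, did not pass either (12 of 25 positive, camera adjusted p = 0.818). Within them Hmox1, haem oxygenase 1, rose 3.02-fold when adjusted over the list alone (log2 fold change 1.59, SE 0.27), but did not pass over all features (limma adjusted p = 0.222). Nqo1 had a value of 0.46 (SE 0.26) and Cbr1 one of 0.27 (SE 0.11). Cytochrome P450 and flavin monooxygenase genes gave a camera adjusted p of 0.789, with -0.50 (SE 0.11) for Cyp4a1, -0.47 (SE 0.15) for Cyp2d1 and 0.12 (SE 0.14) for Cyp2e1, the isoform that oxidises small halocarbons.

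DNA repair (camera adjusted p = 0.991) and cell cycle genes (0.95) did not pass. Fancd2 stood 2.14-fold higher (limma adjusted p = 0.359). Values were -0.28 (SE 0.07) for Chek2, whose other probe gave 0.24, and 0.63 (SE 0.21) for Ccnd1, 0.29 (SE 0.10) for Ccne1 and -0.17 (SE 0.09) for the proliferation marker Mki67. In the unfolded protein and integrated stress response list (camera adjusted p = 0.515), Nupr1, a stress-induced transcriptional regulator, fell by 1.74 on the log2 scale (SE 0.30) when adjusted over the list alone. Over all features Nupr1 did not pass (limma adjusted p = 0.222). Psat1 had a value of -0.22 (SE 0.06). Heat shock proteins (0.647), sterol biosynthesis (0.789), gluconeogenesis and renal metabolism (0.789) and extracellular matrix and fibroblast genes (0.243) did not pass, nor did immediate early genes (0.206), all by camera adjusted p. Single values were 0.51 (SE 0.13) for Cryab, -0.66 (SE 0.19) for Dhcr7, -0.50 (SE 0.13) for Gatm, 0.79 (SE 0.23) for Mmp2 and -0.39 (SE 0.12) for Klf6.

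None of the other lists of cell type markers passed. Proximal tubule transporters had a median of -0.09 over 35 members (camera adjusted p = 0.106), which was 0.01 under quantile normalization. Values were -0.33 (SE 0.07) for the sulphate exchanger Slc26a1, -0.29 (SE 0.07) for the organic anion transporter Slc22a6 and -0.08 (SE 0.06) for the phosphate transporter Slc34a1. The camera adjusted p was 0.345 for thick ascending limb markers, 0.302 for distal tubule and collecting duct markers, 0.206 for podocyte markers, 0.879 for endothelial markers and 0.647 for lymphocyte markers. The thick ascending limb gene Umod had a value of -0.57 (SE 0.34). The endothelial adhesion gene Esam rose 1.51-fold when adjusted over the list alone, but did not pass over all features (limma adjusted p = 0.251). Markers of neighbouring tissue gave 0.647 for perirenal fat and 0.647 for inner medulla, and the adrenal list, with 4 members measured, was not tested.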

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

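The alternatives with scan day, or with only named features, were chosen after seeing the data. Quantile normalization gave 10 changed features, 9 shared with the main count of 9. Median centring, array weights and the deposited series table each gave 9, all shared. Under the alternatives no called feature changed sign, nor did the median of any of the 5 lists that passed. Called features lost the threshold 98 times and kept it 101 times, and these lists lost it 23 times and kept it 102 times. Of 80 named features, Cdkn1a, Cyp2e1, Lcn2 and Slc34a1, none of them called, changed sign under 1 alternative each, and C4a and Rgcc passed with trend and robust.

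Normexp gave 5 changed features and 0 lowered. Without a filter 2 changed, 2 were raised, 0 lowered, 2 at least 2-fold, and 4 lists were lowered; 48892 features were then tested. With each probe by itself 4 lists were lowered. Slide as a fixed block gave 0 changed, 0 raised, 0 lowered and 0 at least 2-fold, with 5 lists raised, and only slides with both groups gave 0 for all 4 counts; both fits have 2 residual degrees of freedom, and limma counted 3511 and 3527 features at an unadjusted p under 0.05. Trend and robust gave 17 changed and 8 lowered. Array weights gave 1 list raised. An estimated correlation gave 0 lists raised and 0 lowered, and fry 0 and 0. Scan day as a fixed block gave 2 changed, 2 raised, 0 lowered and 2 at least 2-fold. Scan day 1 alone, 2 arrays against 2, gave 0 for all 4 counts (2470 at an unadjusted p under 0.05). Only named features gave 3 changed, 3 raised, 0 lowered and 2 at least 2-fold, since 6 of the 9 have no symbol. Apart from the degrees of freedom and the number of features, the cause was not tested.

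Leaving out 1 array gave 1 to 8 changed, 1 to 8 raised, 0 to 2 lowered, 1 to 8 at least 2-fold, 0 to 4 lists raised and 2 to 5 lists lowered. The fatty acid oxidation list passed camera in each of these fits, at a largest adjusted p of 1.32e-05 with the preset correlation; with an estimated correlation over all 6 arrays its adjusted p = 0.443. The preset test also passed this list in 3 of the splits that mix the groups. RT1-CE15 passed in each, at adjusted p from 0.00469 to 0.0255; Vps52 passed in none, and RT1-A3 only without control replicate 3.

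The labels number replicates 1 to 3 in both groups. Deviations from the group means correlated at -0.189, 0.260 and 0.163 for equal numbers, and not every array correlated best with its own number. This gives no clear sign that the numbers pair the arrays, but 3 arrays per group are too few to exclude a pairing. The pair at 0.260 also shares slide 1. The replicate block gave 0 changed, 0 raised, 0 lowered and 0 at least 2-fold in limma (3462 at an unadjusted p under 0.05), and 1 list raised; the glutathione (median 0.08) and inflammatory (median 0.16) lists then did not pass. Signal over background limits dim genes: 59.2% to 67.7% of probes were well above it, and the fold of RT1-A3 is only a lower bound.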

Other observations

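Tests in this part that were chosen only after the result was seen are those of the RT1 neighbourhood, of the slide for RT1 genes, Vps52 and liver transcripts, of the fatty acid oxidation score per array, and of the proximal tubule share. The gene families and the genes named with them were also chosen after seeing the data. Most ribosomal protein genes had slightly lower values in treated arrays. Of 47 Rpl genes 45 were lower in treated arrays (median log2 fold change -0.14, camera adjusted p = 2.9e-08 over 373 families grouped by symbol; adjusted p = 0.996 with an estimated correlation). Of 36 Rps genes 31 were lower (median -0.14, camera adjusted p = 0.000273; adjusted p = 0.996 with an estimated correlation). The medians were -0.06 and -0.05 under quantile normalization. Of 32 RT1 genes 25 were higher (median 0.16, camera adjusted p = 4.24e-06, and adjusted p = 0.996 with an estimated correlation), with a median of 0.40 within slide 1 and 0.03 within slide 2. This family holds RT1-CE15 and RT1-A3, which were called above, so that its test partly restates those calls. The family was not tested without them. Values that did not pass were 0.66 (SE 0.07) for RT1-CE16, 0.63 (SE 0.07) for RT1-DOb and 0.88 (SE 0.13) for RT1-CE3. Other genes at low p, none passing the adjusted threshold, were Fkbp5, a target of the glucocorticoid receptor (-0.88, SE 0.11, adjusted p = 0.183), the natural killer receptor gene Klri1 (-1.13, SE 0.17) and the clock gene Per1 (-1.51, SE 0.31).

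The 6 arrays can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split gave 9 changed features, 7 of them at least 2-fold, and 5 lists; the highest of the other splits gave 763, 297 and 7. As many as in the real split were found in 2, 2 and 4 of the splits, the real one included. The split with 763 features, far above the real count of 9, sets slide 1 against slides 2 and 3, which points to a structure of the arrays by slide. With slide as a fixed block the real comparison gave 0 changed features in limma (3511 at an unadjusted p under 0.05), with 2 residual degrees of freedom, while the differences themselves were 2.87 for RT1-CE15 (2.84 without the block) and 0.94 for Vps52 (0.92 without it).

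All 3 named genes that were called lie in or beside the RT1 region, and Sprague-Dawley rats are outbred. An effect of slide is argued against for RT1-CE15 and Vps52, whose differences within slides 1 and 2 were at least 1.00 of the main ones and exceeded the gaps of 0.17 and 0.09 between the controls of slide 1. Their calls rest on small spreads within groups on these same arrays, so that this is not independent support. Each of these slides holds 1 treated array. RT1-A3, dim in controls, was not tested. A general interferon or antigen-presentation response is argued against by 22 genes of that response outside the region. Their log2 fold changes lay between -0.14 and 0.27, including B2m at -0.05, with a median of 0.03. The 95% bootstrap interval of -0.015 to 0.062 resamples genes, which share the same 6 arrays, and does not measure the spread between animals. Inherited RT1 differences between the animals may be the source, which no genotype here tests: among genes not called, 6 of 133 in the region and 343 of 11291 elsewhere had an unadjusted p under 0.01 (odds ratio 1.51, exact interval 0.54 to 3.41), which leaves it open. A local effect of treatment is open as well.

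Fatty acid oxidation genes were lower in treated arrays, with a median of -0.327. A lower share of proximal tubule cells may contribute: the median lies below that of the transporters (difference -0.24, two-sided permutation p = 0.00104, 100000 permutations of genes, which are not independent), but only 16 of 35 transporters had a 95% limma interval wholly above the list's median, and 8 were lower and 0 higher at an unadjusted p under 0.05 (16, 4 and 0 under quantile normalization, with a transporter median of 0.01). The values do not exclude slide. With slide as a fixed block the list's median was -0.291, and the list passed camera at the preset correlation. Without the block it did not pass with an estimated correlation (camera adjusted p = 0.443). The list's score per array differed by -0.27 with the block (95% interval of a linear model -0.66 to 0.12, 2 residual degrees of freedom) and by -0.30 without it. The score was 0.17 and 0.23 in the controls of slide 1, -0.01 in the control of slide 2, and -0.14, -0.17 and -0.18 in dibromoethane replicates 1 to 3. The split by slide moved the list by -0.172. All the other splits also carry part of the group difference. Those with control replicates 1 and 2 together moved the list by -0.207 and -0.198. Those with control replicates 1 and 3 together gave -0.030, -0.000 and -0.006, and the rest 0.091, 0.087 and 0.056. Time of day of sampling may contribute: clock genes high at the start of the active phase had a median of 0.35 (7 of 8 higher, Per1 the exception) and those of the opposite phase one of -0.09 (0 of 5 higher), a difference of 0.44, short of the 0.5 set in advance; it was 0.13 without dibromoethane replicate 3, 0.85 without dibromoethane replicate 1, 0.59 without dibromoethane replicate 2 and 0.43 to 0.51 without 1 control. An effect of treatment remains open beside these.

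Akr1d1 and Ugt2b1, enzymes made in liver, were not well above background on any control array and at least 3.0-fold higher in treated arrays (limma adjusted p = 0.201 and 0.222; at least 1.9-fold each within slide 1, and 8.3-fold and 9.1-fold within slide 2, which holds dibromoethane replicate 1), and Fabp1 and Fgg were higher too. Slide stays open: over 23 liver-abundant transcripts the median difference was 1.06 within slide 1 (22 higher) and 1.24 within slide 2 (23 higher), against a gap of 1.12 between the controls of slide 1, and over the 19 of them well above background on all arrays 0.53 and 1.08, against 0.95. Liver tissue carried over with the cortex may be a source. Of 23 liver-abundant transcripts, 22 were higher in treated arrays, Alb by 1.86 (SE 0.93) and Ttr by 3.08 (SE 0.98). They were listed after the 4 genes were seen, and none of them is in another list. Their median of 0.63 (95% bootstrap interval over genes, not animals, 0.44 to 1.48) missed the 1 set in advance. That median mixes transcripts bright and dim in control cortex, and so cannot decide the question. Serpinc1 (control log2 level 6.58) differed by 0.11 and Apoc3 (3.13) by 0.08. Among dim members, Cyp2c13 (-5.06) differed by 3.18, Apoa2 (-4.76) by 2.01 and Cyp3a2 (-4.45) by 0.63. Of the 23, 19 were well above background on all 6 arrays. Relative to each gene's mean the list stood at -1.33, -0.07 and -0.30 in control replicates 1 to 3 and at 1.51, 0.26 and -0.02 in dibromoethane replicates 1 to 3, so that it varied within groups as well. Expression in the kidney itself was not excluded.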
